A study of Homo sapiens with 15 samples.

How the data were processed

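RNA of HaCaT and SK Mel-28 cells was hybridised to 15 dual-colour Agilent 4x44K arrays with 41000 probes. Per the labels' protocols, cells grew overnight in 2 ml of medium with 2 percent serum and were then treated for 4 h, total RNA was taken with a column kit, and the sample was labelled with Cy5 and a pool of 6 control cultures of the same line with Cy3. Each control array carried 3 of those 6 cultures in Cy5, so a control array reads the dye bias with a sample that is part of its own reference. Per the labels' treatment protocol 3 cultures were pooled per treatment, while the series text gives 4, so the number pooled is uncertain. No dye was swapped. The arrays lay on 4 slides: the HaCaT controls and both direct HaCaT ZnO arrays on 1 slide, the HaCaT TiO2 arrays and the SK Mel-28 controls on another, the 4 SK Mel-28 particle arrays on a slide of their own, and the ZnCl2 arrays and the Transwell array on the last, which had no controls.

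The deposited files of the single arrays held scanned intensity values per spot, namely mean signals and local background medians, which per the file headers came from Agilent Feature Extraction and had not been normalised. The same files held processed intensity values, which per the file headers were background-subtracted, detrended and dye-normalised, and a log10 ratio of the processed Cy5 over Cy3 signal, per the file headers. Flags for spots well above background, saturation and outlier status were taken from the same deposited files. The deposited series table held a log2 ratio per probe: it equalled the log10 ratio of the files converted to log2 to within 5e-10, ran from -5.11 to 8.22 with a median of 0 in each column, and had 8.26 to 16 percent of spots at 0. The last slide was read with another version of the extraction software than the rest, per the file headers, and the other array steps of the authors are not given in the sources used here.

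The values reported here were computed from the scanned mean signals. Background was corrected with normexp and an offset of 50 and the log2 ratios of Cy5 over Cy3 were normalised within each array by loess, with control spots and outlier-flagged spots given no weight, using limma 3.58.1 in R 4.3.3. Tables and figures used Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9. Spots flagged as outliers were left out and replicate spots averaged, which left 288 probes without a value on some array, and 5374 probes that were well above background on no array in either channel were left out. No spot was saturated, 69.4 to 80.6 percent of spots lay well above background in Cy5 and 66.8 to 77.4 percent in Cy3. Probes were named from their accessions (25564), current symbols (2696) or older symbols (819), 11921 were left unnamed, and the deposited gene name of 5428 probes differed between 2 versions of the array annotation. Where a gene had several probes, as 7658 genes did, the probe with the highest mean intensity stood for it, which gave 26121 features, 16966 named and 9155 unnamed. For genes named in the text 110 values of further probes were compared with the probe used: 107 had the same sign, 80 lay within 1 log2 unit and 78 passed the threshold.

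Single treatments were tested in 1 limma fit of group means over all 15 arrays, with the control pairs of both lines as the only replicates (2 residual degrees of freedom, prior 2.927, prior SD 0.064). The p-value of a lone array assumes that it would have varied as the control pairs did. Both arrays of a control pair lay on 1 slide and were drawn from their own reference, so variation between slides, days or treated cultures is not in the error and these p-values may be too small. Mean changes over both lines were tested in an additive fit of line and treatment over 14 arrays, all but the Transwell array (7 residual degrees of freedom, prior 3.657, prior SD 0.094). The 4 TiO2 and 4 ZnO arrays were each set against the 4 controls with line in the model. The line check compared Cy5 levels of the 2 control arrays of each line after quantile adjustment of the mean intensities. Tests were moderated and limma's p-values were adjusted over all features by Benjamini and Hochberg, with a call at an adjusted p under 0.05, and list counts were also adjusted over the list alone. Within each line the control arrays correlated at 0.559 (HaCaT) and 0.563 (SK Mel-28), with an SD of their difference of 0.138 and 0.128, and no feature had identical values. Correlations of any 2 arrays ran from -0.0134 to 0.622.

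The 26 gene lists were written before the data were examined and hold 10 to 34 members each, some of them not measured, such as HSPA1B, HSPA7 and HSPE1 of the heat shock list and SLC30A8 of the zinc transporters. They cover metallothioneins, zinc transporters, heat shock, NRF2, unfolded protein response, immediate early genes, p53, apoptosis, cytokines, proteasome, cholesterol synthesis, hypoxia, cell cycle, histones, short-lived regulators, autophagy, metal handling, endocytosis, interferon, ribosomal proteins, keratinocyte markers and differentiation, and markers of melanocytes, fibroblasts, blood cells and endothelium. For both lines together they were tested with camera at a preset correlation of 0.01 and with the correlation estimated from the data beside it. For single arrays the list median was set against 10000 random lists of the same size matched on mean intensity in 20 bins, as a percentile without a p-value. Of 286 such medians 91 lay outside the central 95 percent, where 14.3 would by chance if list members varied independently. Members of a list can vary together without a treatment, so the excess alone does not show treatment effects. The genes named were chosen from a pool set by a rule made before the data were examined. The pool held up to 12 rises and 8 falls by size among called features with a current symbol and a signal above background. It also held every metallothionein, zinc transporter and heat shock gene and up to 4 members of each other list. Comparisons of treatments or over both lines added up to 8 called genes each way, and the line check added the keratinocyte and melanocyte lists. Not every gene of the pool is named in the text. In the line check a fold against a group that was not well above background is given as a lower bound.

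On simulated data with 200 changed features, changes of 0.5, 1 and 2 log2 units were recovered 0, 155 and 194 times for a single array against controls, 0, 0 and 185 times for the line difference, 115, 192 and 199 times for both lines, 148, 194 and 200 times for 4 TiO2 arrays against 4 controls and 0, 185 and 198 times for the line check. None of these was called in the wrong direction, and at most 12 unchanged features were called. The simulated noise followed the fitted variance, with no effect of slide or culture, so these rates may not hold for the real arrays. Overlaps and correlations of treatments that share controls were set against simulated unchanged treatments with the same sharing. Alternatives were the processed signals, the deposited ratios, no background correction, scaling of the ratios between arrays, no subtraction of the control arrays, no filter on dim probes, the mean over the probes of a gene, an intensity trend in the prior variance, the slide as a random or fixed block, the replicate number as a block, an estimated correlation in camera and leaving out each array in turn. The line difference at 1 µg/cm2, the 2 comparisons of SK Mel-28 ZnO with the TiO2 arrays of its slide and the fits without the last slide were added after the data were seen. Other time points and doses were not analysed here. Results that need some of the measured items are not reported here.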

Results

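The series measured RNA levels in human skin-derived cells after 4 h with metal oxide nanoparticles or a dissolved zinc salt. HaCaT is an immortalised keratinocyte line and SK Mel-28 is a melanoma line. Each of the 15 dual-colour arrays carried the sample in Cy5 and a pool of untreated RNA of the same line in Cy3. Each line had 2 control arrays and 1 array per treatment: ZnO at 1 and 5 µg/cm2, TiO2 at 5 and 10 µg/cm2 and ZnCl2 at 100 µM. HaCaT had 1 further array, for ZnO at 5 µg/cm2 kept apart from the cells by a Transwell, a porous membrane insert. Per array, 69.4 to 80.6 percent of spots lay well above background in Cy5, and 26121 features were tested, of which 16966 carried a gene symbol. Changes are on the log2 scale with the standard error (SE) of limma's fit, for 1 treated array against 2 control arrays of the line unless stated. No treatment was repeated within a line, so each p-value assumes that a lone treated array varied as the control pairs did, and the small number of arrays limits the precision.

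The control arrays first checked the labels of the lines. Keratins and other epithelial genes stood far higher in HaCaT, and pigment cell genes far higher in SK Mel-28. Among 27 measured keratinocyte markers all 27 were higher in HaCaT, among them KRT5, a basal keratin, KRT6A, a keratin of stressed epidermis, and TP63, a regulator of stratified epithelium. KRT5 differed by at least 926-fold, KRT6A by at least 972-fold and TP63 by at least 232-fold, since none of these was well above background in SK Mel-28. Among 26 melanocyte and melanoma markers 25 were higher in SK Mel-28, including MLANA at -8.99 ± 0.05, PMEL at -8.96 ± 0.05 and TYR, the first enzyme of melanin synthesis, at -8.50 ± 0.05 (HaCaT minus SK Mel-28, n = 2 arrays each). RAB38, a GTPase of melanosome transport, was the exception at 0.88 ± 0.05. In all, limma called 16772 features at an adjusted p under 0.05, 8576 higher in HaCaT and 8196 higher in SK Mel-28. The control arrays of the 2 lines lay on different slides.

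In HaCaT, direct ZnO at 5 µg/cm2 raised HMOX1, 26 of 28 heat shock genes, all 12 metallothionein genes and 29 of 32 immediate early genes within 4 h. HMOX1, which encodes the heme-degrading enzyme heme oxygenase 1, rose by 7.79 ± 0.09 (adjusted p = 4.83e-05). The heat shock genes HSPA1A, HSPA6 and DNAJB1 rose by 6.43 ± 0.09, 5.80 ± 0.10 and 5.105 ± 0.06. ATF3, a stress-induced transcription factor, rose by 5.12 ± 0.07, the chemokine gene CXCL8 by 5.12 ± 0.10, the MAP kinase phosphatase gene DUSP1 by 4.83 ± 0.09 and the cytokine gene IL11 by 4.72 ± 0.10. HERPUD1, a gene of endoplasmic reticulum protein disposal, rose by 4.70 ± 0.07, ZFP36, which shortens the life of cytokine mRNAs, by 4.60 ± 0.07 and ERRFI1, an inhibitor of the EGF receptor, by 4.57 ± 0.07. NR4A1, an early response nuclear receptor, rose by 4.88 ± 0.07 on the probe used, while a further probe of it read 0.21 and did not pass. The largest falls were those of CYP1B1, a cytochrome P450, at -3.12 ± 0.11, and FADD, an adaptor of death receptors, at -3.12 ± 0.07. SOX2, a stem cell transcription factor, fell by 2.87, S1PR5, a sphingolipid receptor, by 2.73, RRS1, a ribosome assembly factor, by 2.70, and RIPK4, a kinase of keratinocyte differentiation, by 2.51. limma called 7237 features, 3492 higher and 3745 lower, and 1141 of them changed at least 2-fold (764 higher, 377 lower). The HaCaT ZnO arrays shared a slide with the HaCaT controls, and after scaling of the ratios between arrays the count was 3053.

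The gene lists showed how wide this response was. All 12 metallothionein genes, which encode small zinc-binding proteins, rose, from MT1M at 4.02 ± 0.12 to MT3 at 0.57 ± 0.06. MT4 rose by 1.82 ± 0.09 and MT1L by 1.35 ± 0.13, but neither was well above background in the controls, so these sizes are uncertain. MT1 genes are close in sequence and a probe may bind several of them, so values of single members are uncertain. Of 23 zinc transporter genes 4 rose and 2 fell: the zinc exporter gene SLC30A1 rose by 3.78 ± 0.08 and the importer gene SLC39A10 fell by 1.00. Of 28 heat shock genes 26 rose, with DNAJA4 at 4.42, HSPH1 at 3.72, BAG3 at 2.83 and HSP90AA1 at 2.42. Of 31 genes of the NRF2 and oxidative stress list 22 rose and 1 fell, with TXNRD1, a thioredoxin reductase, at 3.76, the cystine importer gene SLC7A11 at 2.79 and the ferritin gene FTL at 2.52. Of 27 genes of the unfolded protein and integrated stress response 23 rose and 1 fell, with DNAJB9 at 3.70 and PPP1R15A at 3.55. Of 32 immediate early genes 29 rose and 1 fell, with FOS at 4.41. Of 30 cytokine and NF-kappaB target genes 20 rose and 2 fell, with PTGS2 at 3.19 and CSF2 at 2.93. Adjusted over the list alone, the counts were 25 and 1 for the NRF2 list, 30 and 1 for the immediate early genes and 22 and 3 for the cytokines, and did not change for the other lists named so far.

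Of 31 G2/M and S phase genes 19 fell and 6 rose, with the mitotic kinase genes BUB1B, PLK1 and AURKA falling by 1.71, 1.63 and 1.62. Of 29 ribosomal protein genes 17 fell and none rose (23 fell adjusted over the list alone), with RPL5 at -0.58. Where the controls were not subtracted RPL5 turned to a rise of 0.07, and a further probe of it read -0.16 and did not pass. Of 24 p53 target genes 10 rose and 4 fell, with PLK3 at 3.83 and CDKN1A, a cell cycle inhibitor, at 2.23. Of 24 apoptosis regulators 11 rose and 4 fell, with MCL1, which restrains apoptosis, at 1.71. Of 23 cholesterol synthesis genes 12 rose and 2 fell, with INSIG1, a sterol sensor gene, at 1.30. Of 25 hypoxia and glycolysis genes 14 rose and 3 fell, with ANGPTL4 at 2.62 and the vessel growth factor gene VEGFA at 1.97. Of 28 short-lived transcriptional regulators 15 rose and 8 fell, with MAFF at 3.09. Of 20 autophagy and lysosome genes 8 rose and 1 fell, with GABARAPL1 at 2.43 and SQSTM1 at 2.20. Keratinocyte markers went both ways, with 9 of 27 rising and 5 falling (KRT15 by 1.07), as did keratinocyte differentiation genes, with 5 of 23 rising and 3 falling (FLG by 0.84). In other lists 7 of 28 endocytosis and actin genes rose and 2 fell, 3 of 17 histone genes rose and 3 fell, 3 of 19 metal handling genes rose and 2 fell, and 4 of 23 interferon genes rose and 2 fell. Of 31 proteasome genes 2 fell, of 26 melanocyte markers 4 rose and 1 fell, of 12 fibroblast markers 2 rose and 1 fell, of 14 blood cell markers 1 rose, and of 7 endothelial markers none passed limma's test. Adjusted over the list alone, the rises and falls were 12 and 4 for apoptosis regulators, 15 and 3 for hypoxia, 16 and 9 for short-lived regulators, 9 and 2 for endocytosis, 4 and 3 for histones, 4 and 1 for interferon genes and 1 and 0 for fibroblast markers, with 0 for proteasome genes and blood cell markers and no change for the rest.

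At 1 µg/cm2 ZnO raised a small set of these genes in HaCaT. HMOX1 rose by 4.55 ± 0.09 (adjusted p = 0.00067), and 9 of 12 metallothionein genes rose, from MT1M at 3.05 ± 0.12 to MT1E at 2.33 ± 0.07. HSPA6 rose by 1.98 ± 0.10, HSPA1A by 1.39 ± 0.09 and SLC30A1 by 1.38 ± 0.08. ENTREP1, a gene of endosomal membranes, rose by 2.10 ± 0.11 on the probe used, while 2 further probes read 0.63 and 0.50 and did not pass. limma called 20 features higher and 0 lower (2658 at an unadjusted p under 0.05, of which 1085 were lower). Heat shock genes counted 2 of 28 rising and 13 adjusted over the list alone, NRF2 genes 2 of 31 and 17, metallothionein genes 9 of 12 and 11. All 20 features also rose at 5 µg/cm2, against 2.67 for independent lists. Simulated unchanged treatments that share the controls gave 0, but such treatments give few calls at all, so this 0 does not test the sharing. Across features the changes at the 2 doses correlated at r = 0.443 against 0.333 from the shared controls alone (covariance 0.0324 against 0.00305). Without HaCaT control 1 the count was 8, without control 2 it was 10, and with the processed signals of the scanner software it was 0.

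**Figure D1:**
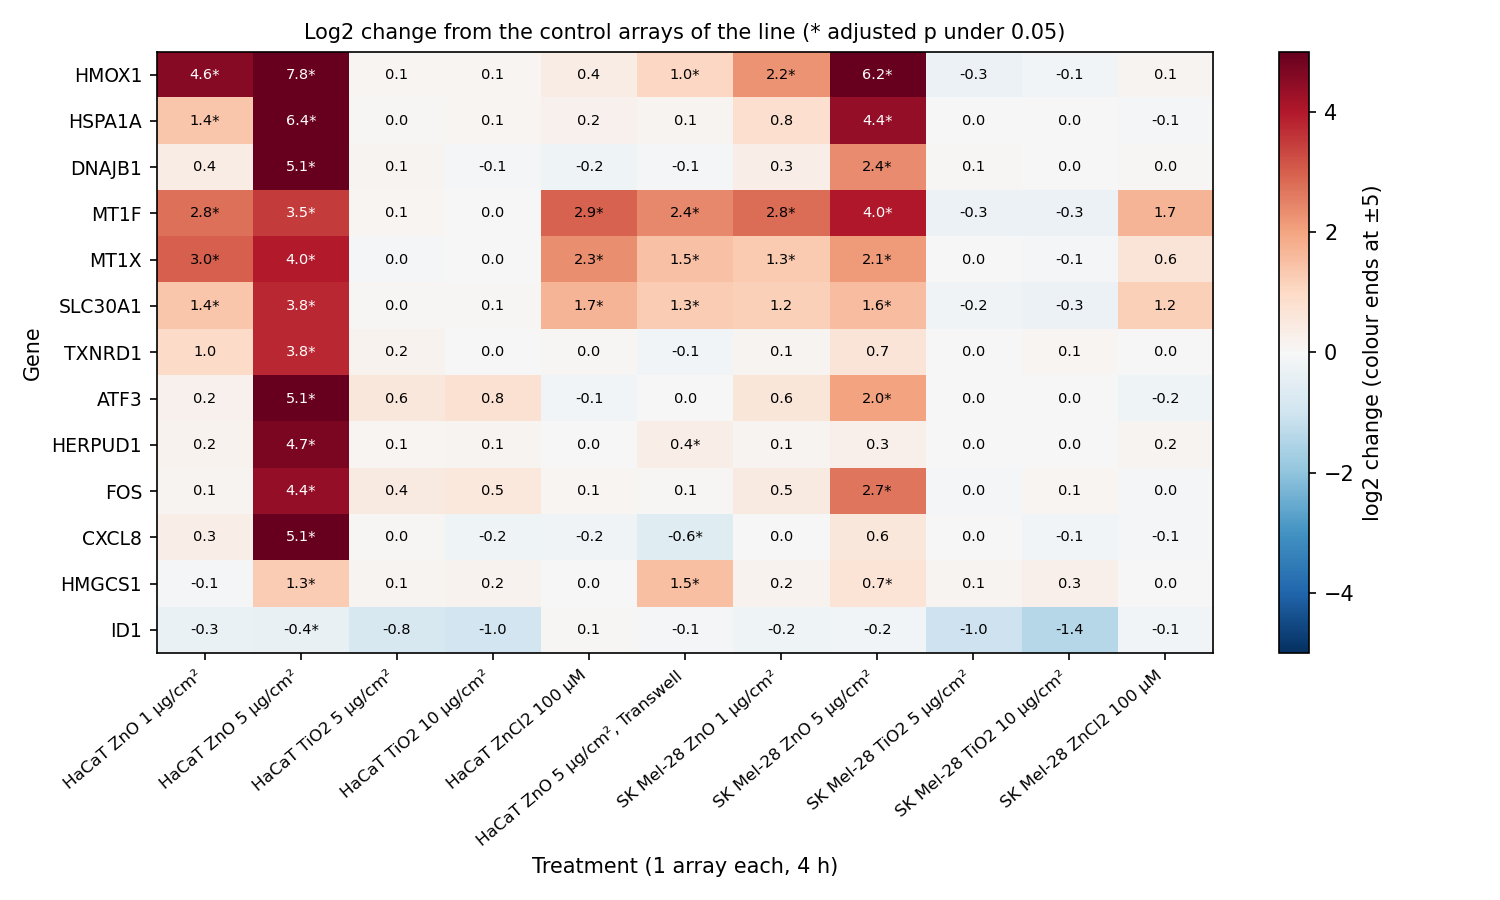
Log2 change of 13 genes (rows) for each of the 11 treatments (columns, 1 array each), with a star where the adjusted p lay under 0.05. HMOX1 read 7.79 in HaCaT and 6.25 in SK Mel-28 after ZnO at 5 µg/cm2, while HMGCS1 was highest, at 1.50, across the Transwell.

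In SK Mel-28, ZnO at 5 µg/cm2 raised HMOX1 by 6.25 ± 0.09 (adjusted p = 0.000465), HSPA1A by 4.41 ± 0.09 and MT1F by 3.99 ± 0.07. Immediate early genes rose with them, EGR2 by 3.02 ± 0.08, FOS by 2.67 ± 0.06, EGR1 by 2.47 ± 0.08 and FOSB by 2.24 ± 0.08, as did GADD45B, a growth arrest gene, by 2.29 ± 0.07. HSPA6 rose by 2.59 ± 0.10, DNAJB1 by 2.38 ± 0.06, ATF3 by 2.02 ± 0.07, SLC30A1 by 1.55 ± 0.08, IL11 by 1.38 ± 0.10 and GCLM, an enzyme of glutathione synthesis, by 1.35 ± 0.06. Falls were led by KLF2, an early response transcription factor, at -1.31 ± 0.12 on the probe used (a further probe read -0.26 and did not pass) and LRIG3 at -1.17 ± 0.10. ID2, an inhibitor of differentiation factors, fell by 1.13, MYB, a proliferation transcription factor, by 1.09, BAMBI, a TGF-beta pseudoreceptor, by 1.05, and IRF4, a transcription factor of pigment cells, by 0.90. limma called 252 features, 213 higher and 39 lower. By list, 22 of 32 immediate early genes rose and 1 fell (26 and 1 adjusted over the list alone), 11 of 28 heat shock genes rose (22), 7 of 12 metallothionein genes rose (9), 4 of 31 NRF2 genes rose (8), 4 of 27 stress response genes rose (8, with 1 fall) and 4 of 30 cytokine genes rose (8, with 2 falls). Of 23 interferon response genes 2 fell, the signalling factor IRF9 by 0.74 (0.03 on a further probe, which did not pass) and the ubiquitin-like ISG15 by 0.73, and 15 fell adjusted over the list alone.

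The SK Mel-28 particle arrays lay on another slide than the SK Mel-28 controls, so slide and particle treatment cannot be told apart in that comparison. Without HaCaT control 1 or 2 the count of 252 was 64, without SK Mel-28 control 1 it was 82 and without control 2 it was 96, and with the processed signals it was 0. Set against the 2 TiO2 arrays of its own slide, a comparison added after the data were seen, ZnO at 5 µg/cm2 gave 211 calls (185 higher, 26 lower), with HMOX1 at 6.46 ± 0.09, HSPA1A at 4.40 ± 0.09, MT1F at 4.28 ± 0.07 and EGR2 at 3.07 ± 0.08, and SLC39A10 fell by 0.76. That count was 56 without HaCaT control 1 or 2 and 114 without either SK Mel-28 control. In this within-slide comparison 19 of 32 immediate early genes rose and 1 fell, and 11 of 28 heat shock genes and 7 of 12 metallothionein genes rose, while 0 of 23 interferon genes passed limma's test. At 1 µg/cm2 limma called 7 features higher and 0 lower (1628 at an unadjusted p under 0.05): MT1F rose by 2.78 ± 0.07 (adjusted p = 0.0073), HMOX1 by 2.24 ± 0.09 (adjusted p = 0.0345), MT1G by 1.40, MT1X by 1.29, MT1H by 1.24, MT1B by 1.20 and MT2A by 1.18. SLC30A1 read 1.19 ± 0.08 with an adjusted p of 0.086, and against the TiO2 arrays of the slide it rose by 1.43 ± 0.08 among 9 calls. All 7 features called at 1 µg/cm2 also rose at 5 µg/cm2 in the line, against 0.0571 for independent lists. The count of 7 was 0 without HaCaT control 1 or 2 or SK Mel-28 control 1, and 1 without SK Mel-28 control 2, and the count of 9 was 0 or 1 without each of the same arrays.

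The lines differed in the size of the response to ZnO at 5 µg/cm2. HaCaT rose further by 4.55 ± 0.14 for CXCL8 (adjusted p = 0.00122), 4.43 ± 0.09 for HERPUD1, 4.30 ± 0.09 for the co-chaperone gene DNAJA4, 4.04 ± 0.12 for DUSP1, 3.91 ± 0.09 for OVOL1, an epithelial transcription factor, and 3.35 ± 0.11 for the chemokine gene CCL26. KLF2 differed by 4.42 ± 0.17 on the probe used and by 0.31 on a further probe that did not pass. CYP1B1 differed by -3.25 ± 0.16, FADD by -2.44 ± 0.11 and SOX2 by -2.37 ± 0.13. MT1E differed by 3.30 ± 0.10 while MT1F, the metallothionein gene with the largest rise in SK Mel-28, differed by -0.49 ± 0.10. limma called 3636 features for this difference, 1866 with the higher change in HaCaT and 1770 with the lower. Leaving out each control array in turn gave 1832 and 1702 for HaCaT controls 1 and 2 and 2079 and 2013 for SK Mel-28 controls 1 and 2. The count was 1240 with the processed signals and 371 after scaling between arrays. The HaCaT ZnO arrays shared a slide with their controls and the SK Mel-28 ZnO arrays did not. A slide effect thus cannot be told apart from a line difference in these counts. The 2 responses still shared genes: 194 features rose in both lines against 28.5 for independent lists, 22 fell in both against 5.59, and 11 went opposite ways, with r = 0.464 across features against -0.00488 in simulated unchanged groups. At 1 µg/cm2 a test of the line difference, added after the data were seen, called 7 genes, all higher in HaCaT, with HMOX1 at 2.31 ± 0.13, MT1E at 2.29 ± 0.10 and MT1A at 1.85 ± 0.10, each at an adjusted p of 0.0499, and it called 0 without any 1 of the 4 control arrays. The difference between the lines in the response to ZnCl2 gave 0 calls in limma, with 2556 features at an unadjusted p under 0.05.

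**Figure D2:**
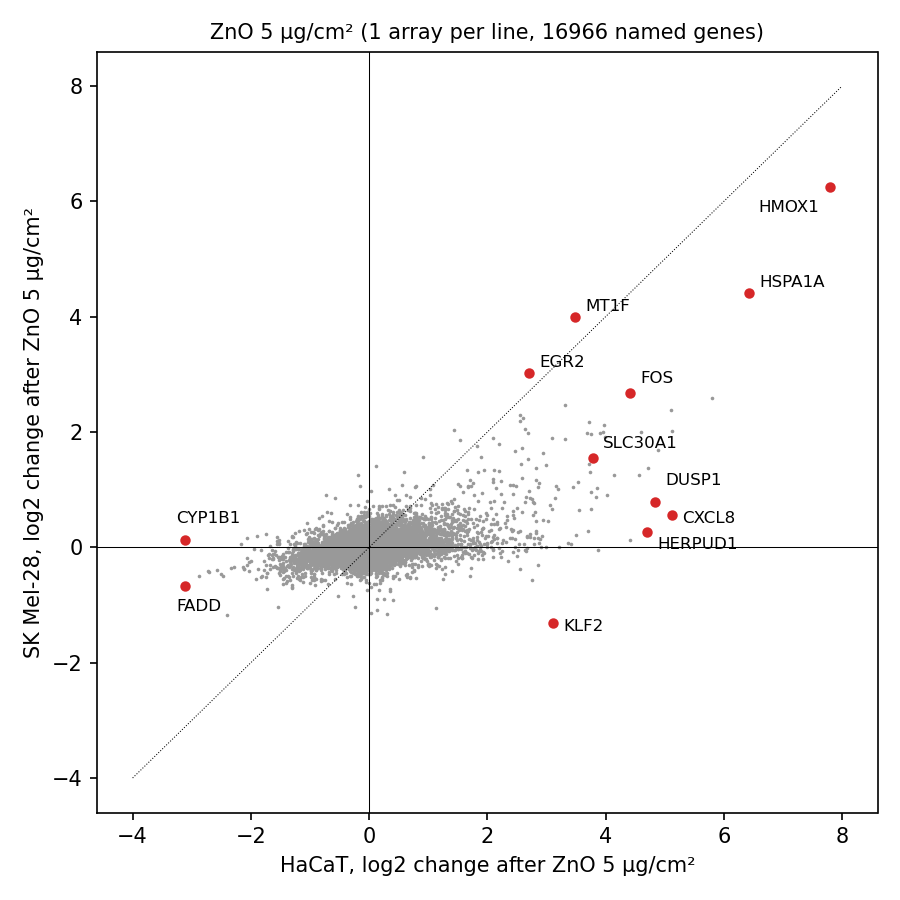
Each point is a named gene, with its log2 change after ZnO at 5 µg/cm2 in HaCaT on the horizontal axis and in SK Mel-28 on the vertical axis, 1 array per line; the dotted line marks equal change. HMOX1 lay at 7.79 and 6.25, while CXCL8 rose by 5.12 in HaCaT and read 0.56 in SK Mel-28, where it did not pass.

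Fitting both lines together, with line and treatment as additive terms over 14 arrays, gave the mean change over both lines. Its error held the differences between the lines over all treatments. A call in this fit does not show a response in each line: CXCL8 passed at 2.84 ± 0.79, with 5.12 in HaCaT and 0.56 in SK Mel-28, where it did not pass. After ZnO at 5 µg/cm2 HMOX1 rose by 7.02 ± 0.42 (adjusted p = 1.73e-05), HSPA1A by 5.42 ± 0.34, MT1F by 3.74 ± 0.25 and FOS by 3.54 ± 0.31. GADD45B rose by 2.43 ± 0.11 (adjusted p = 4.74e-06; 2.56 in HaCaT and 2.29 in SK Mel-28) and GCLM by 1.50 ± 0.09 (adjusted p = 1.73e-05; 1.65 and 1.35). FADD fell by 1.90, LRIG3 by 1.79, S1PR5 by 1.57 and the ribosome factor RRS1 by 1.56. limma called 2395 features, 1274 higher and 1121 lower. The count was 771 and 803 without HaCaT control 1 and 2, 1094 and 1222 without SK Mel-28 control 1 and 2, 742 without the HaCaT ZnO array and 8006 without the SK Mel-28 ZnO array, and 940 with the processed signals. Of the 26 lists 15 passed camera with a preset correlation of 0.01, and none with an estimated correlation. Immediate early genes (25 of 32 rose, 28 adjusted over the list alone) had an adjusted p of 2.84e-26, and adjusted p = 0.254 with an estimated correlation. Heat shock genes (22 of 28, 26 adjusted over the list alone) had 9.36e-21 and metallothionein genes (9 of 12, 12 adjusted over the list alone) had 7.77e-12, each with adjusted p = 0.254 with an estimated correlation. Ribosomal protein genes (7 of 29 fell, 19 adjusted over the list alone) had 1.04e-09, with adjusted p = 0.254 with an estimated correlation, and cell cycle genes (6 of 31 fell, 17 fell and 2 rose adjusted over the list alone) had 3.68e-05, with adjusted p = 0.324 with an estimated correlation. The NRF2 list (9 of 31 rose, 15 with 1 fall adjusted over the list alone) and the unfolded protein list (7 of 27 rose, 17 adjusted over the list alone) both had 4.56e-09, with adjusted p = 0.324 with an estimated correlation.

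ZnO at 5 against 1 µg/cm2 over both lines asked which genes followed the dose. HSPA1A rose by 4.31 ± 0.39 (adjusted p = 0.000799), HMOX1 by 3.62 ± 0.48, FOS by 3.25 ± 0.36, EGR2 by 2.86 ± 0.23, GADD45B by 2.16 ± 0.13 (adjusted p = 8.17e-05) and CCN1, a matricellular growth gene, by 1.54 ± 0.13. LRIG3 fell by 1.72 and OTX1, a homeobox gene, by 1.14 (-0.10 on a further probe, which did not pass). limma called 162 features, 129 higher and 33 lower. No metallothionein gene was among them at an adjusted p under 0.05, in a fit whose error also held the differences between the lines. The metallothionein median was still higher at 5 than at 1 µg/cm2, at 3.61 against 2.82 in HaCaT and 1.9 against 1.18 in SK Mel-28. The count was 25 without the HaCaT array at 1 µg/cm2, 213 without the HaCaT array at 5, 44 without the SK Mel-28 array at 1 and 6594 without the SK Mel-28 array at 5, and it was 98 with the slide as a block and 30 with the processed signals. The lower dose alone, over both lines, gave 2 calls, MT1F at 2.77 ± 0.25 (adjusted p = 0.0104) and ENTREP1 at 1.68 ± 0.18 (adjusted p = 0.0228; 2 further probes read 0.62 and 0.60), with 964 features at an unadjusted p under 0.05. ZnO and TiO2 at the matched dose of 5 µg/cm2 differed at 778 features, 536 higher and 242 lower after ZnO, with HMOX1 at 7.11 ± 0.48, HSPA1A at 5.40 ± 0.39, JUN at 2.96 ± 0.39 and GADD45B at 2.46 ± 0.13 (adjusted p = 1.83e-05), and HILPDA, a lipid droplet gene, lower by 1.30 ± 0.28. That count was 508 without the HaCaT ZnO array, 55 without the HaCaT TiO2 array, 7177 without the SK Mel-28 ZnO array and 117 without the SK Mel-28 TiO2 array, and 112 with the slide as a block. A fit of all 4 ZnO arrays against the 4 controls called 0 features in limma, with 2084 at an unadjusted p under 0.05.

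TiO2 left no feature past the threshold in either line. limma called 0 features for each of the 4 arrays, and 2030 (HaCaT, 5 µg/cm2), 2317 (HaCaT, 10 µg/cm2), 1776 (SK Mel-28, 5 µg/cm2) and 2521 (SK Mel-28, 10 µg/cm2) had an unadjusted p under 0.05, where chance gives 1306.1. By size, the largest values in HaCaT were those of ID2, at -1.69 ± 0.07 and -1.63 ± 0.07 at the lower and higher dose, and EGR1, at 1.03 ± 0.08 and 1.34 ± 0.08. In SK Mel-28 they were IFIT1, an interferon-induced gene, at -1.24 ± 0.15 and -1.32 ± 0.15, and ID1, at -1.04 ± 0.07 and -1.42 ± 0.07. HMOX1 and the metallothionein genes did not pass on any TiO2 array, and the metallothionein median lay between -0.09 and 0.03. The 4 TiO2 arrays together, against the 4 controls with line in the model, gave 2 lower features: ID1, an inhibitor of differentiation factors, fell by 1.06 ± 0.10 (adjusted p = 0.0258, lower on 4 of 4 TiO2 arrays than on any control), and the unnamed probe A_32_P149011 fell by 0.67 ± 0.05 (adjusted p = 0.00804). Over both lines at 10 µg/cm2 the same features passed, ID1 at -1.19 ± 0.12 (adjusted p = 0.0218) and the probe at -0.72 ± 0.08. TiO2 at 5 µg/cm2 and TiO2 at 10 against 5 µg/cm2 gave 0 calls in limma over both lines, with 1135 and 723 features at an unadjusted p under 0.05.

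The ID1 call was fragile while its size was not. Across alternatives the 4 against 4 value lay between -1.12 and -0.95, and its adjusted p was 0.287 with the processed signals, 0.299 with the deposited ratios and 0.0501 after scaling between arrays. It was also lost without each single array but the SK Mel-28 TiO2 array at 10 µg/cm2: the adjusted p was 0.0518 and 0.142 without HaCaT control 1 and 2, 0.0506 and 0.26 without the HaCaT TiO2 array at 5 and 10, 0.149 and 0.146 without SK Mel-28 control 1 and 2, and 0.123 without the SK Mel-28 TiO2 array at 5. Over both lines at 10 µg/cm2 leaving out each control or TiO2 array in turn gave 0 calls, except 19 calls without the HaCaT TiO2 array. Each TiO2 array lay on another slide than the controls of its line. At 10 µg/cm2 over both lines 4 lists passed camera at the preset correlation: ribosomal protein genes were lower (median -0.14, adjusted p = 2.83e-10), as were interferon response genes (median -0.20, adjusted p = 1.19e-06) and keratinocyte differentiation genes (median -0.10, adjusted p = 0.041), and cholesterol synthesis genes were higher (median 0.08, adjusted p = 0.0373). With the slide as a fixed block 10 lists passed at the preset correlation: ribosomal protein genes were lower (adjusted p = 5.62e-10) and cholesterol synthesis genes higher (adjusted p = 0.00589), while keratinocyte differentiation genes had an adjusted p of 0.0604 and interferon genes turned in direction with an adjusted p of 0.979. None of the 4 lists passed without a preset correlation, with adjusted p = 0.769 with an estimated correlation for the first 3 and adjusted p = 0.977 with an estimated correlation for the cholesterol list. In this fit over both lines no gene of these lists passed limma's test, adjusted over the list alone or over all features. On the single SK Mel-28 TiO2 arrays some interferon genes did fall, adjusted over the list alone. The interferon median was -0.273 and -0.291 in SK Mel-28 at 5 and 10 µg/cm2, and 0.0202 and -0.0546 in HaCaT.

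**Figure D3:**
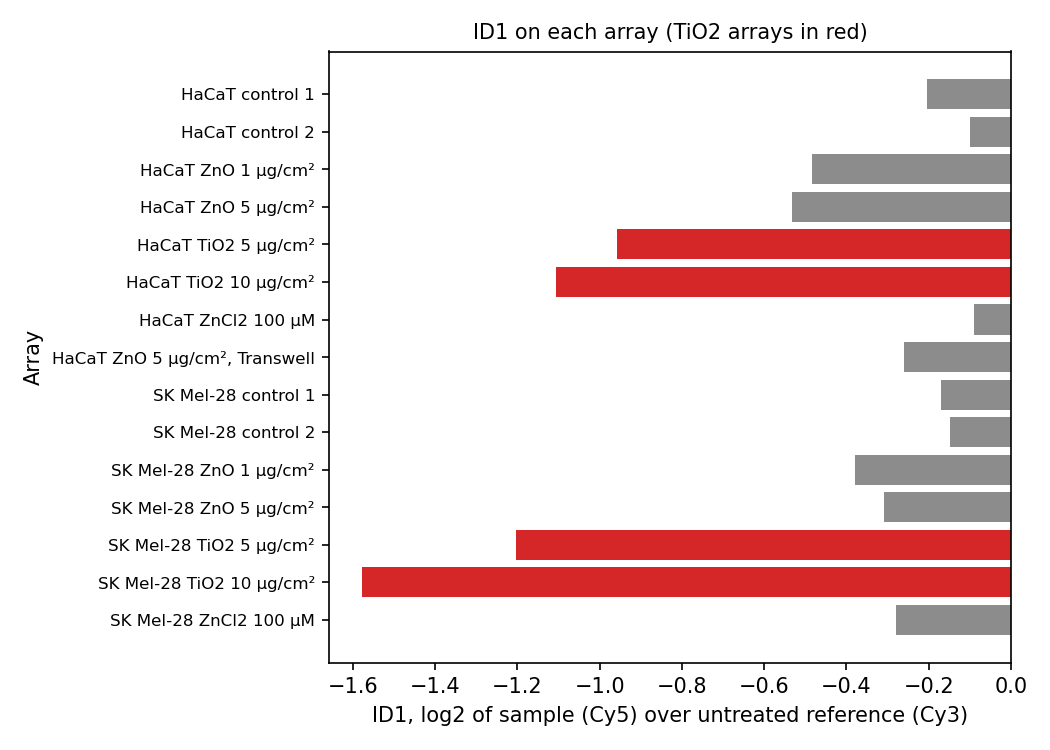
Log2 ratio of ID1, sample over untreated reference, on each of the 15 arrays, before the controls are subtracted. The 4 TiO2 arrays (red) lay between -1.58 and -0.96 and the 11 others (grey) between -0.53 and -0.09.

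Dissolved zinc, given as ZnCl2 at 100 µM, set the particles against zinc ions. In HaCaT 8 of the 14 calls were metallothionein genes: MT1F rose by 2.93 ± 0.07 (adjusted p = 0.00221), MT1M by 2.58 ± 0.12, MT1G by 2.48 ± 0.06 and MT2A by 2.25 ± 0.07, with 8 of 12 members called (9 adjusted over the list alone). SLC30A1 rose by 1.69 ± 0.08, CARHSP1, an RNA-binding protein gene, by 1.40 ± 0.06, ANP32D by 1.25 ± 0.08 and DNAJC7, a co-chaperone gene, by 1.22 ± 0.06. HMOX1 read 0.38 ± 0.09 with an adjusted p of 0.225. limma called 14 features higher and 0 lower (4019 at an unadjusted p under 0.05), and the count was 0 without HaCaT control 1 or 2 and with the processed signals. Of the 14 features 11 also rose with ZnO at 1 µg/cm2, against 0.0107 for independent lists. The 0 for simulated unchanged treatments that share the controls does not test the sharing, as such treatments give few calls. In SK Mel-28 no feature passed in limma (3330 at an unadjusted p under 0.05), where MT1F read 1.68 ± 0.07 (adjusted p = 0.0866) and SLC30A1 1.21 ± 0.08 (adjusted p = 0.303), and 7 of 12 metallothionein genes were higher adjusted over the list alone. Against ZnCl2, ZnO at 5 µg/cm2 gave 6377 calls in HaCaT (3002 higher, 3375 lower) and 128 in SK Mel-28 (121 higher, 7 lower). HMOX1 was higher by 7.42 ± 0.11 and 6.12 ± 0.11 in the 2 lines, and HSPA1A by 6.20 ± 0.10 and 4.47 ± 0.10. MT1F was higher by 0.57 ± 0.08 and 2.31 ± 0.08, but after scaling between arrays it was lower in HaCaT, at -0.89. The zinc response was not matched: metallothionein medians after ZnO and ZnCl2 were 3.61 and 2.27 in HaCaT and 1.9 and 0.61 in SK Mel-28. Particles and a higher level of dissolved zinc thus cannot be told apart in these differences. The HaCaT count was 2109 after scaling between arrays, and the SK Mel-28 count was 25 without HaCaT control 1 or 2, 78 without either SK Mel-28 control and 0 with the processed signals.

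Over both lines ZnCl2 called 223 features, 211 higher and 12 lower, led by MT1F at 2.30 ± 0.25 (adjusted p = 0.00164). The rest were of smaller size: FBXL17, a ubiquitin ligase gene, rose by 0.91 ± 0.10, CKB, a creatine kinase gene, by 0.91 ± 0.12, the synapsin gene SYN1 by 0.86 ± 0.08 and the transcription factor gene SOX1 by 0.80 ± 0.07. Further probes of these 4 genes read between -0.07 and 0.07 and did not pass. The ribosomal protein genes RPL26, RPLP0 and RPL7A fell by 0.35, 0.33 and 0.32. The count was 140 and 179 without HaCaT control 1 and 2, 147 and 155 without SK Mel-28 control 1 and 2, 0 without the HaCaT ZnCl2 array and 211 without the SK Mel-28 one, and 400 with the slide as a random block. Ribosomal protein genes (2 of 29 fell, 12 adjusted over the list alone) had a camera adjusted p of 7.77e-17, with adjusted p = 0.368 with an estimated correlation, and metallothionein genes (1 of 12 rose, 7 adjusted over the list alone) had 1.32e-07, with adjusted p = 0.964 with an estimated correlation. The ZnCl2 arrays and the Transwell array lay on a slide without controls, scanned later and read with another version of the extraction software. Slide and treatment thus cannot be told apart in their counts against the controls or against arrays of other slides. A difference in the untreated reference of that slide would enter each log ratio of its arrays.

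**Figure D4:**
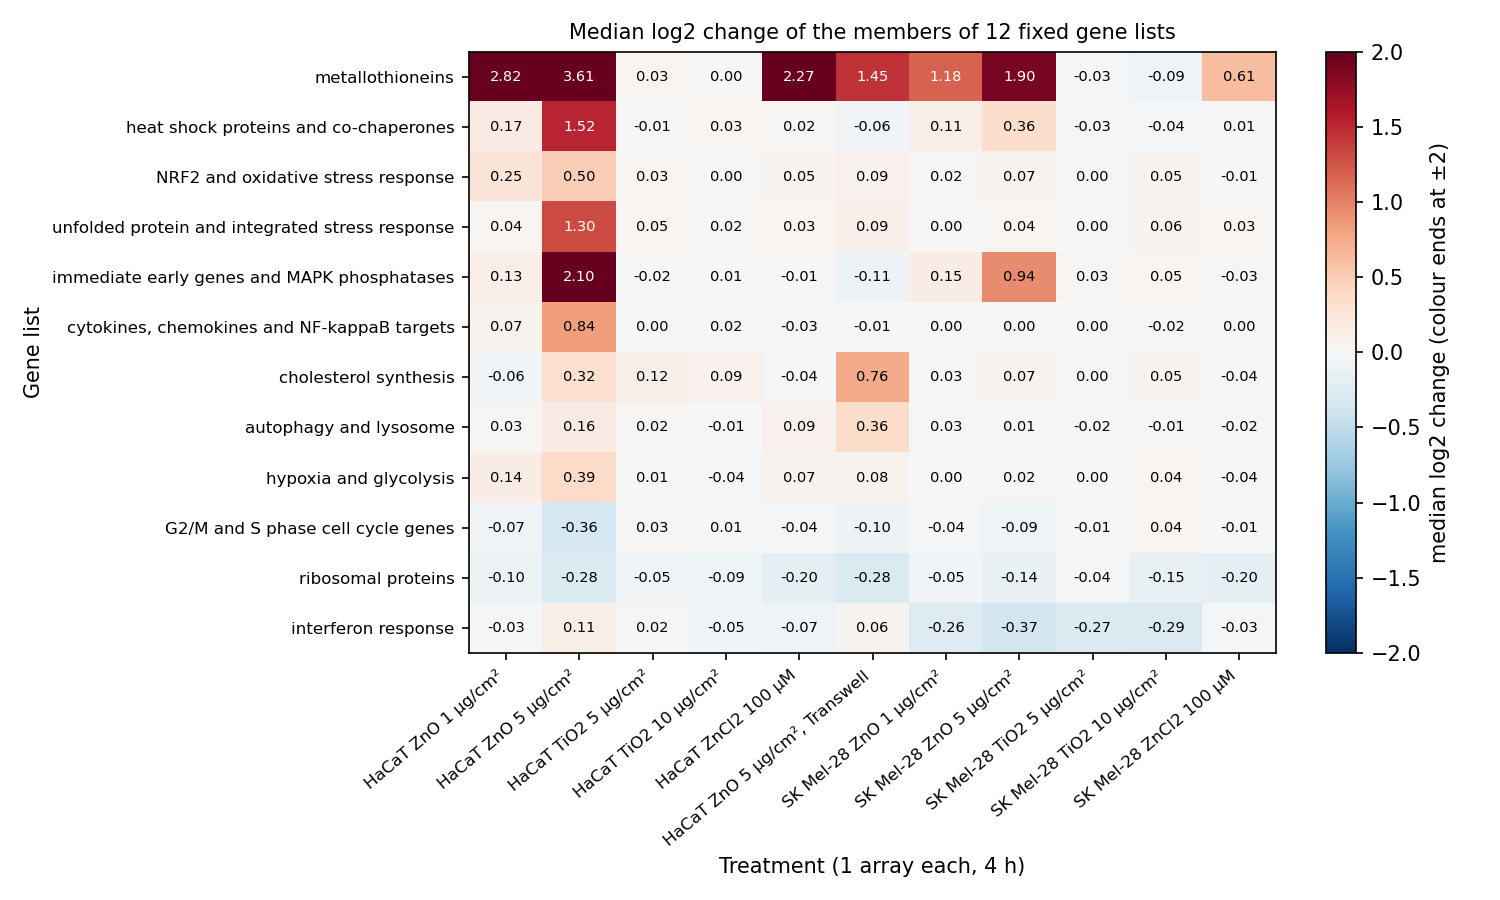
Median log2 change of the measured members of 12 of the 26 gene lists (rows) for each of the 11 treatments (columns, 1 array each). The metallothionein row read 3.61, 2.27 and 1.45 in HaCaT after direct ZnO at 5 µg/cm2, ZnCl2 and ZnO across the Transwell, and the cholesterol row read 0.32, -0.04 and 0.76.

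ZnO at 5 µg/cm2 across a Transwell asked what reached HaCaT cells without particle contact. Metallothionein genes rose, with MT1F at 2.39 ± 0.07 (adjusted p = 0.0114) and MT1E at 1.00 ± 0.07 at the ends of 9 of 12 called members, and SLC30A1 rose by 1.26 ± 0.08. Cholesterol synthesis genes rose as a group: 20 of 23 were called (22 adjusted over the list alone), among them HMGCS1, an enzyme of the mevalonate route, at 1.50 ± 0.07, and MVD, another, at 1.27 ± 0.08. The ubiquitin-like gene UBD rose by 1.89 ± 0.11, the calprotectin gene S100A8 by 1.78 ± 0.10, the plasminogen activator gene PLAT by 1.73 ± 0.06, the metalloproteinase gene MMP12 by 1.60 ± 0.13 and the autophagy and p53 target gene TP53INP1 by 1.57 ± 0.12. FLG, the filaggrin gene of the skin barrier, fell by 1.75 ± 0.09 on the probe used and by 1.32 on a further probe, while another read -0.06 and did not pass. The cytokine gene IL1B fell by 1.28, EREG, an EGF receptor ligand gene, by 1.27 and DKK1, a Wnt inhibitor gene, by 1.16. Autophagy and lysosome genes counted 11 of 20 rising (14 adjusted over the list alone) and NRF2 genes 10 of 31 (12), with HMOX1 at 1.05 ± 0.09. Heat shock genes went both ways, with 3 of 28 rising and 5 falling (6 and 8 adjusted over the list alone), and so did immediate early genes, with 3 of 32 rising and 8 falling (3 and 9). Ribosomal protein genes fell, 7 of 29 (19 adjusted over the list alone), and of 27 keratinocyte markers 7 rose and 1 fell (9 and 2).

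limma called 2380 features across the Transwell, 1511 higher and 869 lower, of which 74 changed at least 2-fold. This count rested on the control arrays: it was 0 without HaCaT control 1 or 2 and 583 without either SK Mel-28 control, and 0 with the processed signals and 58 after scaling between arrays. The labels place these cells inside the insert with the particles outside it, and no culture in an insert without particles was among the samples. Direct ZnO against ZnO across the Transwell gave 6968 calls, 3103 higher and 3865 lower with contact, with HMOX1 higher by 6.74 ± 0.11 (adjusted p = 7.82e-05), HSPA1A by 6.31 ± 0.10, CXCL8 by 5.72 ± 0.12 and MT1F by 1.11 ± 0.08, and S1PR5 lower by 3.08 ± 0.10, FADD by 3.06 ± 0.09 and the chemokine receptor gene ACKR3 by 2.82 ± 0.13. After scaling between arrays that count was 2386. The direct and the Transwell array differed in contact but also in the insert and the slide, so contact cannot be told apart from these. The 2 exposures shared 445 rises (202 for independent lists) and 356 falls (125), with 316 features called in opposite directions, and correlated at r = 0.174 across features against 0.325 from the shared controls alone (covariance 0.0194 against 0.00295). On the slide of the Transwell array, ZnCl2 against ZnO across the Transwell gave 70 calls, 24 higher and 46 lower. FLG was higher after ZnCl2 by 1.71 ± 0.11 (adjusted p = 0.0367), while 2 further probes of it read 0.99 and 0.26 and did not pass, IL1B by 1.18 ± 0.10 and MT1G by 1.00 ± 0.07, while UBD was lower by 1.80 ± 0.13, PLAT by 1.65 ± 0.07, HMGCS1 by 1.52 ± 0.08 and the chemokine gene CCL2 by 1.38 ± 0.07. Of 23 cholesterol synthesis genes 11 were lower after ZnCl2, with a median of -0.78, and of 12 metallothionein genes 4 were higher. The count of 70 was 0 without any 1 of the 4 control arrays and with the processed signals.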

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

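The tests of the Transwell array, of ID1 within the SK Mel-28 particle slide, of the slide of the interferon pattern and of the ZnO splits were chosen only after the result was seen, as was the line difference at 1 µg/cm2.

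The responses of the 2 lines, with 1 treated array each, differed by a test of the difference itself. For ZnO at 5 µg/cm2 that test called 3636 features, and at 1 µg/cm2 it called 7. Only the HaCaT ZnO arrays shared a slide with their controls, so a slide effect cannot be told apart from a line difference. The Cy3 reference channel, which no comparison of the report uses alone, also held differences between slides. Within HaCaT 14126 features of the reference differed between the last slide and the others (903 of them at least 2-fold), and 0 differed between the first 2 slides in limma. In SK Mel-28 10772 differed between the last slide and the others (503 at least 2-fold), and 1334 between the particle slide and the control slide (0 at least 2-fold). Per the labels the reference on every slide was a pool of untreated RNA of the line, and whether the last slide had a pool of its own is not given in the sources used here. Such a difference would enter each ZnCl2 and Transwell log ratio, and it was checked for HMOX1 alone.

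Interferon response genes read lower on the 4 SK Mel-28 particle arrays, with list medians of -0.255 and -0.372 after ZnO at 1 and 5 µg/cm2 and -0.273 and -0.291 after TiO2 at 5 and 10 µg/cm2. An offset of the control arrays, or the dye bias that they read on their own slide, was not the whole cause. Before the control arrays were subtracted the median over the arrays was -0.303 (arrays from -0.308 to -0.206), while the control arrays read 0.0737. The reference pool held the same control cultures, so a high interferon level in those cultures would remain in this ratio and was not tested. A dye bias of the particle slide alone would remain in it as well and was not tested. Another reference preparation was argued against as well, since the list's median Cy5 level changed by -0.369 (quartiles -0.545 to -0.161) and its Cy3 level by 0.00204. The median after ZnCl2, on another slide, was -0.0307 (quartiles -0.0988 to -0.00411), but all particle arrays of the line lay on 1 slide, so slide and particles cannot be told apart.

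The array across the Transwell differed from its controls at 2380 features, 20 of the 23 cholesterol synthesis genes among them. Its slide was not the whole cause for the cholesterol genes, which differed by a median of -0.78 (quartiles -0.95 to -0.553) in the HaCaT ZnCl2 array of that slide. It stays open for the breadth: the called features changed in the ZnCl2 array by 0.334 times as much at the median (quartiles 0.1 to 0.596), a ratio that picking called features lowers, and the 2 arrays correlated at 0.53 against 0.331 from the shared controls alone. Dissolved zinc was not the whole cause of the cholesterol change either: after ZnCl2 the cholesterol median was -0.036 (upper quartile 0.00894), against 0.755 (lower quartile 0.519) across the Transwell, while the metallothionein median was higher after ZnCl2, at 2.27 against 1.45. Culture in an insert cannot be told apart from the agent, as the 70 features between the 2 HaCaT arrays of the slide carry both and no untreated insert was there.

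ID1 read lower on all 4 TiO2 arrays than on any control. The particle slide was not the whole cause in SK Mel-28, as the ZnO arrays of that slide lay above its TiO2 arrays by 1.012 ± 0.0732 at 1 µg/cm2 and 1.082 ± 0.0732 at 5 µg/cm2. Hybridisation on the slide of the HaCaT TiO2 arrays was not the whole cause in HaCaT, as the SK Mel-28 controls on it differed from the HaCaT controls by -0.007086 ± 0.0598, but controls of another line cannot show a difference in culture or handling of these samples. Of the 34 splits of the 8 arrays that could be fitted 1 gave as many calls, the real split with 2. The highest count in the others was 0, the split of that slide's 4 arrays from the rest included. Many of the other splits took unequal numbers of arrays from the lines, which makes calls less likely with line in the model. The splits thus do not decide on chance. Arrays that share a line and a group also shared a slide. The count was 0 with the processed signals and ran from 0 to 2 without single arrays. A fall of ID1 with TiO2 in both lines may be tested by repeated cultures with controls on the same slide.

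For the 4 ZnO arrays against the controls the real split gave 0 calls in limma (2084 at an unadjusted p under 0.05), and so did each of the 34 splits that could be fitted, the real one included, so the splits decide nothing about these arrays.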

How the results depend on the processing

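The fits without the last slide and every alternative for the line difference at 1 µg/cm2 and for SK Mel-28 ZnO against the TiO2 arrays of its slide were chosen only after results were seen, and the other alternatives were set before the data were examined. Counts are features called by limma unless lists are named, and the cause was not tested unless stated. Of 473 alternative counts 292 lay within 1.5 times the reported one. Of 2679 alternative values of the genes named in the report 2172 kept direction and side of the threshold, 485 kept the direction but lost the call, 20 gained one and 2 turned: MT1F in HaCaT ZnO at 5 µg/cm2 against ZnCl2 read -0.891 after scaling, and RPL5 in HaCaT ZnO at 5 µg/cm2 read 0.07246 where the controls were not subtracted. Counts within 1.5 times under every alternative run were those of the line check, of TiO2 at 5 µg/cm2 and TiO2 at 10 against 5 µg/cm2 over both lines and of the single-array lists, and for HaCaT ZnO at 5 µg/cm2 under every one but scaling. Where limma gave 0 features under an alternative, 557 to 7831 features had an unadjusted p under 0.05, so a 0 does not show that levels were equal. Signal limited what could be seen, as 69.4 to 80.6 percent of spots per array were well above background in Cy5.

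The Feature Extraction processed signals gave 0 calls for HaCaT ZnO at 1 µg/cm2, HaCaT ZnCl2, the Transwell, SK Mel-28 ZnO at 1 and at 5 µg/cm2 (also against its slide's TiO2 arrays, 0 and 0), SK Mel-28 ZnO against ZnCl2, ZnCl2 against the Transwell, the line difference at 1 µg/cm2, TiO2 at 10 µg/cm2 over both lines and the 4 TiO2 arrays. They gave 4219 for HaCaT ZnO against ZnCl2, 1240 for the line difference at 5 µg/cm2, and over both lines 1 for ZnO at 1 µg/cm2, 940 for ZnO at 5 µg/cm2, 30 for ZnO at 5 against 1, 235 for ZnO against TiO2 and 2 lists for TiO2 at 10 µg/cm2. The deposited ratios of the series matrix values gave 0 for the same comparisons but SK Mel-28 ZnO at 5 µg/cm2, with 58 against control and 81 against the TiO2 arrays, and 2039 for the line difference at 5 µg/cm2, 971 for ZnO at 5 µg/cm2 over both lines, 32 for ZnO at 5 against 1, 234 for ZnO against TiO2 and 2 lists for TiO2 at 10 µg/cm2.

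Without background correction HaCaT gave 31 for ZnO at 1 µg/cm2 and 1 for each TiO2 dose, SK Mel-28 gave 383 for ZnO at 5 µg/cm2, 317 against the TiO2 arrays, 215 against ZnCl2 and 1 for ZnCl2, and the rest were 209 for ZnCl2 against the Transwell, 9 for the line difference with ZnCl2 and 1 for ZnO at 1 µg/cm2 over both lines. Where the dye bias was not subtracted HaCaT gave 712 for ZnO at 1 µg/cm2, 1 and 2 for TiO2 at 5 and 10 µg/cm2, 408 for ZnCl2 and 5593 for the Transwell, and SK Mel-28 gave 15 and 1604 for ZnO at 1 and 5 µg/cm2, 2 for TiO2 at 10 µg/cm2 and 3 for ZnCl2. Scaling between arrays, which shrinks arrays with a wide response, gave 3053 for HaCaT ZnO at 5 µg/cm2, 58 for the Transwell, 150 for SK Mel-28 ZnO at 5 µg/cm2, 2109 for HaCaT ZnO against ZnCl2, 2386 for direct against Transwell ZnO, 0 for ZnCl2 against the Transwell, 371 and 0 for the line difference at 5 and 1 µg/cm2, 5 for ZnO at 1 µg/cm2 and 255 for 5 against 1 over both lines, 1 for the 4 TiO2 arrays and 9 for the 4 ZnO arrays.

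An intensity trend in eBayes gave 1 and 3 for TiO2 at 5 and 10 µg/cm2 in HaCaT and the same numbers in SK Mel-28, 83 and 7 for ZnCl2 in HaCaT and SK Mel-28, 10 and 12 for the line differences with ZnCl2 and ZnO at 1 µg/cm2, and 0 for ZnO at 1 µg/cm2 over both lines. No filter on dim probes (30205 features) gave 1174 for the Transwell, 1 and 146 for SK Mel-28 ZnO at 1 and 5 µg/cm2, 5 for the lower dose against the TiO2 arrays, 0 for ZnCl2 against the Transwell, 0 for the line difference at 1 µg/cm2 and 1 for the 4 ZnO arrays. The mean over the probes of a gene gave 0 for that line difference and 4 for ZnO at 1 µg/cm2 over both lines. Without the slide 4 arrays the both-line fits gave 1 for ZnO at 1 µg/cm2 and 77 for 5 against 1.

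The slide as a random block, with a correlation of -0.164 between arrays of a slide, gave 1 for HaCaT TiO2 at 5 µg/cm2, 3979 for the Transwell, 459 for SK Mel-28 ZnO at 5 µg/cm2, 400 for ZnCl2 over both lines, 1 for the 4 ZnO arrays and 2 lists for TiO2 at 10 µg/cm2. As a fixed block it gave, over both lines, 1 for TiO2 at 10 µg/cm2, 98 for ZnO at 5 against 1, 112 for ZnO against TiO2 and 10 lists for TiO2 at 10 µg/cm2, and it could not be estimated for ZnCl2, the 4 TiO2 arrays or any single treatment. With an estimated correlation camera passed 0 lists for ZnO at 5 µg/cm2, 0 for ZnCl2 and 0 for TiO2 at 10 µg/cm2. The replicate block on the control numbers, which only the line check could carry, gave 16658 in place of 16772. The numbers do not pair the arrays, as the difference of controls 1 and 2 correlated between the lines at -0.022 for Cy5 levels and 0.0442 for log ratios.

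Leaving out 1 array in turn, where the lone array of a pair is assumed to vary like the other pair, gave the following lowest and highest counts. HaCaT ZnO ran from 8 to 19 at 1 µg/cm2 and 5088 to 6086 at 5 µg/cm2, HaCaT ZnCl2 from 0 to 11, the Transwell from 0 to 583, SK Mel-28 ZnO from 0 to 1 and from 64 to 96, and all single TiO2 arrays, SK Mel-28 ZnCl2 and the line difference with ZnCl2 stayed at 0 in limma. ZnO at 5 µg/cm2 against ZnCl2 ran from 5148 to 5363 in HaCaT and 25 to 78 in SK Mel-28, direct against Transwell ZnO from 5774 to 6031, and ZnCl2 against the Transwell gave 0. The line difference ran from 1702 to 2079 at 5 µg/cm2 and was 0 at 1 µg/cm2, and SK Mel-28 ZnO against its slide ran from 0 to 1 and from 56 to 114. Over both lines the ranges were 0 to 2 for ZnO at 1 µg/cm2, 742 to 8006 at 5 µg/cm2, 0 to 19 for TiO2 at 10 µg/cm2, 0 to 211 for ZnCl2, 25 to 6594 for ZnO at 5 against 1 and 55 to 7177 for ZnO against TiO2, with 0 for TiO2 at 5 µg/cm2 and at 10 against 5. The 4 TiO2 arrays gave 0 to 2, the 4 ZnO arrays 0 to 2, the line check 15283 to 16164, the lists 14 to 15, 2 to 5 and 2 to 4 for ZnO at 5 µg/cm2, ZnCl2 and TiO2 at 10 µg/cm2, and the single-array lists 82 to 90 beside 91.

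The share of calls that were higher moved by over 10 points in some of these. For HaCaT ZnO at 1 µg/cm2 it was 87.1 percent without background correction, 83.33 with the trend and 72.05 without subtraction, beside 100. For the Transwell it was 86.21 after scaling and 79.93 without either SK Mel-28 control, beside 63.49. For SK Mel-28 ZnO at 5 µg/cm2 it was 67.24 with the deposited ratios, 65.71 without subtraction, 95.31 without either HaCaT control and 94.79 without SK Mel-28 control 2, beside 84.52, and 65.43 beside 87.68 against the TiO2 arrays with the deposited ratios. Against ZnCl2 it was 82.46 with the trend beside 94.53, and for the line difference at 5 µg/cm2 74.66 after scaling beside 51.32. Over both lines ZnO at 5 µg/cm2 had 68.35 and 68 without HaCaT control 1 and 2 and 70.62 without the HaCaT ZnO array, beside 53.19. ZnO at 5 against 1 had 90 with the processed signals, 90.62 with the deposited ratios, 90.82 with the fixed slide block, 94.81 without slide 4, 100 without the HaCaT array at 1 µg/cm2 and 47.57 without the SK Mel-28 array at 5 µg/cm2, beside 79.63. ZnO against TiO2 had 91.07 with the fixed block, 98.18 and 89.74 without the HaCaT and SK Mel-28 TiO2 array and 47.33 without the SK Mel-28 ZnO array, beside 68.89.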

Other observations

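The tests of HMOX1 against dissolved zinc and the list values below were chosen only after the result was seen.

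The 29 measured ribosomal protein genes had a median log2 ratio to the reference, before the controls are subtracted, of 0.503 and 0.501 on the HaCaT control arrays, 0.390 and 0.188 after ZnO at 1 and 5 µg/cm2, 0.428 and 0.383 after TiO2 at 5 and 10 µg/cm2, 0.260 after ZnCl2 and 0.214 across the Transwell. In SK Mel-28 it was 0.403 and 0.417 on the controls, 0.361 and 0.283 after ZnO at 1 and 5 µg/cm2, 0.344 and 0.248 after TiO2 at 5 and 10 µg/cm2 and 0.178 after ZnCl2. All treatments of a line share the same 2 controls, so the medians below them are not independent of each other. In HaCaT TiO2 at 10 µg/cm2 the median of the 23 keratinocyte differentiation genes, which encode parts of the skin barrier, was -0.191, below all matched random lists, but 0.0276 at 5 µg/cm2, at percentile 77.56. The median of the cholesterol synthesis genes there was 0.124 at 5 µg/cm2 and 0.0873 at 10 µg/cm2, above all matched lists.

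In HaCaT HMOX1 was higher after ZnO at 1 µg/cm2 than after ZnCl2 by 4.176 ± 0.108, with metallothionein medians of 2.82 and 2.27, which were not close enough to match the zinc response of the 2 arrays. The difference stood in the treated channel, with 3.823 in Cy5 and -0.353 in the Cy3 reference. The zinc exporter gene SLC30A1 went against the metallothionein medians, at 1.38 ± 0.08 after ZnO at 1 µg/cm2 and 1.69 ± 0.08 after ZnCl2. Particles and a higher level of dissolved zinc cannot be told apart as the source of the HMOX1 rise, and a series of ZnCl2 doses that brackets the metallothionein response of ZnO would test it.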
